A study of Mus musculus with 4 samples.

How the data were processed

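Chromatin immunoprecipitation with an antibody against PPARγ, the nuclear receptor that drives fat cell formation, was followed by sequencing in 3T3-L1 cells, a mouse preadipocyte line, on day 4 of differentiation. Untreated cells were compared with cells given exosomes, small secreted vesicles, from HTR8 cells, a human trophoblast line made to overexpress PPARγ. The 4 libraries were 1 IP and 1 input library for each condition, and groups were taken from the sample titles.

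Per the submitters' processing notes, CASAVA, fastp 0.19.11 and MACS2 2.1.0 were used. The aligner and the genome build were not given in the sources used here. The authors deposited 1 peak table per condition, with the column order of MACS2 narrow peaks and the nearest annotated transcription start added to each peak. Per the file headers, the authors gave each peak a fold enrichment and a score. In the deposited tables the 2 columns after the fold enrichment carry a spreadsheet error in place of a header. The first of them was read as −log10 p and the second as −log10 q, because the deposited score equalled 10 times the first, rounded down, in 3958 of 3958 and 11357 of 11357 rows, and because the second exceeded the first in 0 rows. The lowest −log10 p was 2.3011 in the exosome list and 2.3027 in the untreated list, just above the 2.301 of a p of 0.005. Fold enrichment, p and q were used to describe, rank and filter peaks within a list, to count the peaks of each list past a threshold, and to recover fragments and background as described next.

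Rows with the same chromosome, start and end were taken as 1 peak, keeping the summit of smallest p. The 3958 exosome rows became 3822 peaks and the 11357 untreated rows became 10883. Starts are printed counting from 1. The number of fragments at each summit and the expected background there were recovered by solving MACS2's published formulas for fold enrichment and Poisson p together. In them the fold enrichment is the fragments plus 1 over the background plus 1, which lowers it below the plain ratio, most of all at small backgrounds. The solution was a whole number of fragments that met the deposited p to within 0.000214 on the −log10 scale in the exosome list and 0.000199 in the untreated list. The lowest background in a list was taken as its genome-wide background, and the narrowest peak as its fragment length. Exact 95% Poisson intervals are given for fragments and 95% Wilson intervals for shares. Both cover counting error only.

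The genes named in the tables were compared with the RefSeq annotation of GRCm38.p6. Of 1372 symbols matched from the exosome list and 2988 from the untreated list, 46.3% and 50.7% had a gene start or end within 1 base of RefSeq's on the same chromosome, and coordinates were therefore read as GRCm38. The 1019 genes named in both tables had the same position in both. RefSeq served for gene names and for deciding which of its 21887 protein-coding genes had a summit in the body or within 10 kb of either end. Distances to transcription starts are those of the deposited tables, which run from the peak midpoint, as was checked for 15312 of 15312 rows. Exons and introns were not separated, because the annotation used here lists gene ends only. The tables give a gene identifier for nearly every peak but a symbol for 1421 of 3406 genes in the exosome list and 3085 of 7217 in the untreated list, a limit on every setting that relies on the named gene.

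With 1 IP library per condition there was no test between conditions, and no p-value is given for any difference between them. Overlap meant at least 1 shared base. Chance levels came from 100 shufflings of each list within its own chromosomes, between the first and the last annotated gene, with bedtools 2.31.1. Shuffled positions were not restricted to mappable sequence. For 15 gene lists written before the data were examined, the number of genes with a peak was placed among 10000 random lists of the same size, matched on gene length in 10 bins. Fragments and background were recovered for 100% of 515 peaks simulated from the same formulas. All of 200 shuffled exosome peaks placed directly on untreated peaks were found. Of 20 lists of 30 genes with 12 planted, 20 passed the 95th percentile, and 2 of 40 random lists did. These checks test the calculation and not the power at effects of the size reported below. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

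Named genes followed a rule set before the data were examined. It took 12 PPARγ and adipocyte genes with or without a peak, the 10 peaks of highest fold enrichment on assembled chromosomes in each list, the 10 shared peaks of highest mean rank, up to 4 genes with a peak from each gene list by highest fold enrichment, and the 10 peaks of highest fold enrichment in 1 list alone. Alternatives were stricter thresholds on q, p and fold enrichment, other definitions of overlap, promoter windows and gene assignment, and equal numbers of the strongest peaks. A search for PPARγ and other motifs at summits was planned and not run, since no genome sequence was used here.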

Results

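PPARγ occupancy was profiled in 3T3-L1 preadipocytes on day 4 of differentiation, in untreated cells and in cells treated with exosomes from PPARγ-overexpressing HTR8 trophoblast cells. The design asks where PPARγ bound and whether exosome treatment changed it. Each condition had 1 IP and 1 input library, so no replicate spread was available and every difference below describes these libraries. Library totals were not used here. The recovered genome-wide background was 2.40 fragments at a position in the exosome IP with a fragment length of 225 bases, and 2.004 in the untreated IP with a fragment length of 198 bases. Per base of fragment, the exosome IP was therefore 1.05 times as deep as the untreated IP. The exosome and untreated inputs were estimated at 1.26 and 1.11 times the depth of their own IP libraries. The estimate is the step size that best fitted the recovered backgrounds. Of the backgrounds used for it, 51.7% and 51.9% lay on that step, against 24.9% and 27.4% with a window 1 base wider, so it is rough.

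Untreated cells had 10883 PPARγ peaks and exosome-treated cells 3822, a ratio of 2.85. The peaks were small in both lists. The median peak rested on 10 fragments in the untreated IP (quartiles 8 and 12) over a background of 3.103, and on 11 in the exosome IP (quartiles 10 and 13) over 3.97. Median fold enrichment was 2.61 (quartiles 2.33 and 2.93) in the untreated list and 2.45 (2.25 and 2.74) in the exosome list, and the highest values were 5.66 and 5.03. Few peaks passed a false discovery threshold in the authors' deposited tables. At a q of 0.05, 162 untreated peaks passed, or 1.49% (95% Wilson interval 1.28 to 1.73%), and 12 exosome peaks, or 0.314% (0.180 to 0.548%). The q was 1 for 19.1% of untreated and 79.9% of exosome peaks. With only untreated peaks as wide as the narrowest exosome peak, the ratio of the lists was 1.79, and at a q of 0.05 it was 13.5. That q was a stricter cut on p in the exosome list. A −log10 p of 7.39 gave a q of 0.051 there, while 6.33 gave 0.048 in the untreated list. At the same −log10 p of 4 in both lists the ratio was 3.15.

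**Figure D1:**
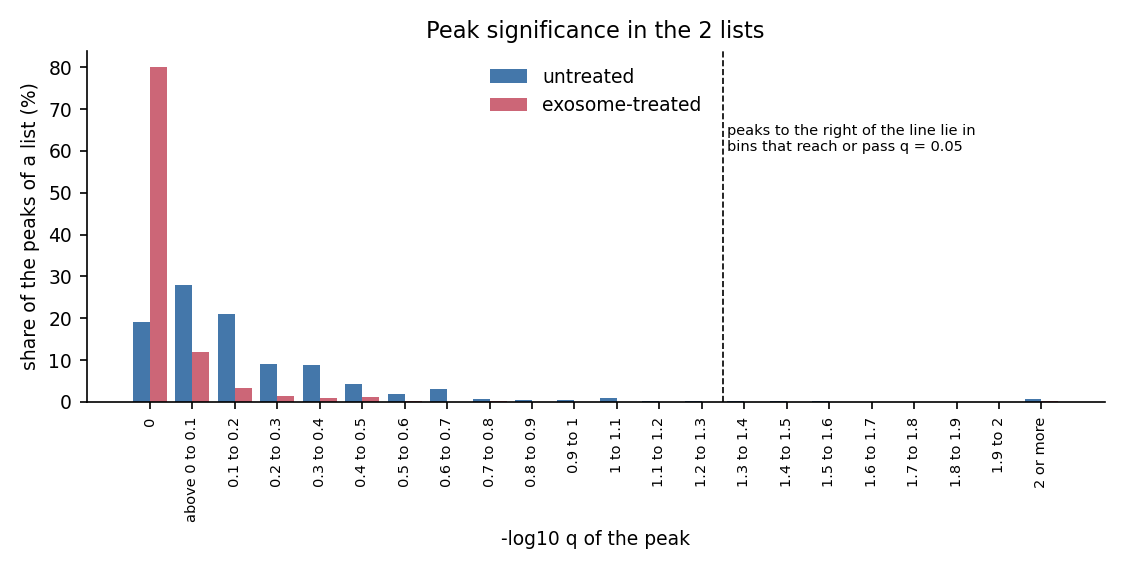
Share of the peaks of each list (vertical axis, percent) by −log10 q of the peak (horizontal axis, bins), for 10883 untreated and 3822 exosome peaks. Bars start at 0, and the dashed line marks the first bin that reaches a q of 0.05. A q of 1 was given to 79.9% of exosome and 19.1% of untreated peaks.

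The strongest untreated peaks lay in or near genes outside the adipocyte lists, and Ubc, of the housekeeping list, was among them. By fold enrichment the leading peak was in Tmtc2 at chromosome 10, 105238387 to 105238626, with a fold enrichment of 5.66 and 16 fragments (95% Poisson interval 9.15 to 26.0) over a background of 2.004. Next came a peak in Hmcn2, which encodes an extracellular matrix protein, at chromosome 2, 31344503 to 31344766, with a fold enrichment of 5.60 and 18 fragments (10.7 to 28.4). The others were a peak at chromosome 8, 123610134 to 123610340 (5.40), whose nearest protein-coding gene, over 10 kb away, was Rhou, and peaks in Ahnak2 (5.33), beside the polyubiquitin gene Ubc (5.30), in Tmem267 (4.99), beside the immunoglobulin receptor gene Fcgr3 (4.86), in the natural killer cell receptor gene Klra3 (4.86), in Sema5b (4.86) and in Osbpl10 (4.66). The chromosome 8 peak and the Fcgr3 peak lay within 1 kb of a tRNA or 5S rRNA gene. The Ubc peak, at chromosome 5, 125383811 to 125385156, held 23 fragments (14.6 to 34.5) over a background of 3.53, with a q of 3.3e-07 in the authors' deposited table.

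The strongest exosome peak lay between genes at chromosome 4, 146272416 to 146272692, with Zfp600 as the nearest protein-coding gene. Its fold enrichment was 5.03, with 24 fragments (15.4 to 35.7) over a background of 3.97. A peak in Tcte3, for which the deposited table names Ermard, at chromosome 17, 15029086 to 15029335, followed at 4.55 with 18 fragments (10.7 to 28.4). A peak in Ppfibp1 had a fold enrichment of 4.42 and a peak in Klhdc4 had 4.12. The other 6 lay over 10 kb from any protein-coding gene. Their nearest genes were Zfp386 (4.42), Rasl11a (4.27), Creb5, Efl1 and Car10 (4.12 each) and Map3k7 (4.09). None of these 20 peaks overlapped the other list, so the strongest peaks of each list were also the strongest in that list alone. Of the 12 exosome peaks at a q of 0.05, 8 lay where the background was over 10 times the genome level, 5 of them in the first 3.1 Mb of chromosome 9. The other 4 were the Zfp600, Tcte3 and Rasl11a peaks and a peak in Pemt, which encodes an enzyme of phosphatidylcholine synthesis, at chromosome 11, 60046282 to 60046538 (fold enrichment 3.83, q 0.022 in the authors' deposited table).

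The lists had few peaks in common. Of the exosome peaks, 13 overlapped an untreated peak, or 0.340% (95% Wilson interval 0.199 to 0.581%), against a mean of 8.28 and a range of 3 to 13 over 100 shufflings. The same pairs made up 0.119% (0.0698 to 0.204%) of the untreated peaks. The shared peaks of highest mean rank by fold enrichment were 5 within genes and 5 over 10 kb from any protein-coding gene. Those within genes lay in Phf14 (2.57 in the exosome and 2.98 in the untreated list), Spag16 (2.313 and 2.97), Fam120c (2.33 and 2.66), the ribosome biogenesis gene Rrp12 (2.29 and 2.64) and Sfi1 (1.95 and 1.76). The others had Rbpms (3.35 and 2.61), Gtf2e2 (2.18 and 3.37), Lhx2 (2.42 and 2.73), Agr3 (2.101 and 2.18) and Arsj (1.98 and 2.23) as the nearest gene. None of these genes belonged to the adipocyte lists. In the Sfi1 pair and the other 3 at least 1 list had a background over 10 times its genome level, and 2 of these 4 pairs lay at Gm10800 and Gm10801 on chromosome 2. No shared peak reached a q of 0.05. Of the 12 exosome and 162 untreated peaks at that threshold, 0 overlapped a peak of the other list, and 3 and 6 had one within 10 kb. None of the 1000 strongest peaks of one list overlapped the 1000 strongest of the other.

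Shared peaks did not lead either list by fold enrichment. In the exosome list 2 of 13 lay above the list's median fold enrichment, with a median of 2.18 against 2.45 for the 3809 peaks in that list alone. In the untreated list 6 of 13 did, with a median of 2.61, equal to that of the 10870 others. By −log10 q, 3 of the 13 lay above the median of the exosome list and 9 of the 13, or 69.2%, above that of the untreated list. The strongest 3822 untreated peaks, as many as the exosome list holds, had a fold enrichment of 2.74 or more, and 3 of them overlapped an exosome peak.

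Peaks of both lists lay in genes more often than shuffled peaks did. Shuffled positions were not restricted to mappable sequence, so the excess need not reflect a preference of PPARγ. Summits in the body of a protein-coding gene made up 51.0% of untreated peaks (95% Wilson interval 50.1 to 52.0%) against 38.2% after shuffling (range 37.2 to 39.6%), and 47.0% of exosome peaks (45.4 to 48.6%) against 38.2% (36.6 to 40.9%). Within 1 kb of a transcription start lay 5.71% of untreated peaks (5.29 to 6.16%) and 5.24% of exosome peaks (4.57 to 5.99%). No shuffled share was taken for transcription starts, so the level reached by chance is not known. The shares within 3 kb were 13.8% and 14.4%. The median distance to a transcription start was 16769 bases in the untreated and 17047 bases in the exosome list.

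The untreated peaks were unevenly spread over the chromosomes. Their density was highest on chromosomes 17 and 11, at 6.40 and 6.29 peaks per Mb, lowest among the autosomes on chromosome 16, at 2.92, and 1.15 on the X. The exosome list ranged from 1.25 peaks per Mb on chromosome 7 to 2.0002 on chromosome 10, with 0.598 on the X. The ratio of untreated to exosome peaks ran from 1.93 on the X to 4.56 on chromosome 17. Neither list had a peak on the Y.

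**Figure D2:**
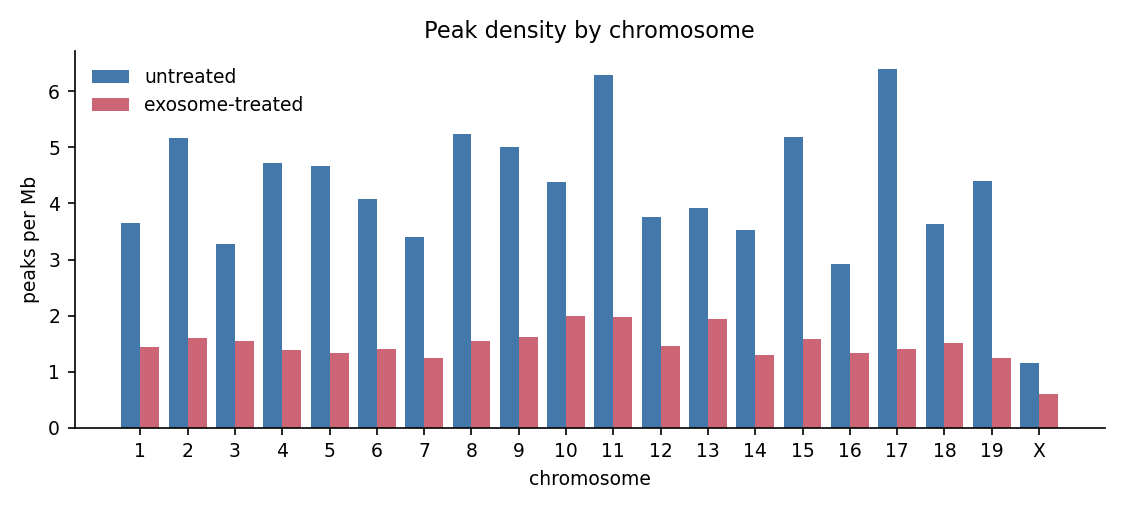
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) in the untreated and exosome lists, over the span from the first to the last annotated gene. Each bar is 1 list of 1 IP library. Chromosomes 17 and 11 had the densest untreated peaks, at 6.40 and 6.29 per Mb. Among the chromosomes shown, the X had the lowest density in both lists. The Y, without a peak in either list, is left out.

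A protein-coding gene with a peak in its body or within 10 kb was found 4688 times in untreated cells, 21.4% of genes, and 2269 times in exosome-treated cells, 10.4%. With equal numbers of peaks, the strongest 3822 of each list, the order turned, with 2057 genes in untreated and 2269 in exosome-treated cells. Shuffled peaks reached a mean of 4387 genes (4226 to 4515) and 1831 genes (1751 to 1937). Peaks of both lists fell at 819 genes, against a mean of 602.2 (559 to 647) after shuffling the exosome peaks and 699.2 expected from independent lists of genes of the same length. Other ways of assigning peaks to genes changed these counts by over 1.5 times. The gene named in the deposited table gave 2944, 1353 and 373 genes in untreated cells, exosome-treated cells and both.

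Most classical PPARγ genes had no peak in either condition. Of the 12 genes named in advance, 10 had none within 10 kb in both lists: the fatty acid binding protein gene Fabp4, the lipid droplet gene Plin1, the adiponectin gene Adipoq, the fatty acid transporter gene Cd36, the lipoprotein lipase gene Lpl, the gluconeogenic gene Pck1, the insulin-responsive glucose transporter gene Slc2a4, the regulators Pparg and Cebpa, and the fatty acid synthase gene Fasn. The lipid droplet gene Cidec had an untreated peak 25 bases upstream of its transcription start, at chromosome 6, 113435671 to 113435900, with a fold enrichment of 2.32, 10 fragments (95% Poisson interval 4.80 to 18.4) over a background of 3.75, and a q of 0.94 in the authors' deposited table. Rxra, which encodes the partner of PPARγ on DNA, had an exosome peak at chromosome 2, 27746751 to 27747033, with a fold enrichment of 2.14, 11 fragments (5.49 to 19.7) over 4.596, and a q of 1.

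Known PPARγ targets carried no more peaks than random genes of the same length. Of 39 targets, 7 had an untreated peak (Agpat2, Klb, Mgll, Cidec, Acsl1, Me1 and Sorbs1), against a mean of 7.94 and a central 95% range of 4 to 13 in random lists, at percentile 36.1. In the exosome list 3 did (Gpd2, Plin2 and Mgll), against 3.75 (1 to 7), at percentile 36.3. Mgll, the monoacylglycerol lipase gene, was the only target with a peak in both, with 3 untreated peaks of a fold enrichment up to 2.61 and 1 exosome peak of 2.63. The exosome peak overlapped none of the untreated peaks, and the nearest untreated summit was 469 bases away. The strongest target peaks lay by the lipid droplet gene Plin2 in the exosome list (3.04, q 0.76 in the authors' deposited table), and in Klb, a coreceptor gene of FGF21 signalling (2.95, q 0.39), and Sorbs1 (2.82) in the untreated list.

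Regulators of fat cell differentiation lay at the upper edge of the random range in the exosome list and near its middle in the untreated list. Of 36, 12 had an exosome peak against 7.16 (3 to 12), at percentile 97.4, and 13 an untreated peak against 12.2 (7 to 17), at percentile 61.8. Ncoa2, Nfia, Ppargc1a, Tcf7l1 and Zfp423 had peaks in both. The strongest was an untreated peak in Cebpd, an early inducer of Pparg, at chromosome 16, 15888605 to 15888839, with a fold enrichment of 3.91, 16 fragments (9.15 to 26.0) over 3.35, and a q of 0.0154 in the authors' deposited table. Klf4 had an exosome peak at chromosome 4, 55525591 to 55525908, with a fold enrichment of 3.65, 17 fragments (9.90 to 27.2) over 3.93, and a q of 0.14. The thermogenic coactivator gene Ppargc1a reached 3.19 in the untreated and 2.51 in the exosome list, and Nfia reached 2.85 and 3.19. These peaks lay at different sites. The summits of the Nfia peaks were 27410 bases apart, and those of Ppargc1a lay 49733 bases or more from any summit of the other list.

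Genes of lipid and glucose metabolism stayed within the central range of random lists. Counts and percentiles are given for the untreated list first. Of 25 lipogenic genes 7 had an untreated and 3 an exosome peak (percentiles 57.5 and 45.7). They were led by Acaca (3.27) and Acacb (2.89), which encode acetyl-CoA carboxylases. Mlxipl (2.35 in the untreated and 2.18 in the exosome list) and Lpin1 (2.34) followed. The Acaca peak lay 9995 bases outside the gene, and the deposited table names Aatf for it. The Mlxipl summits were 9704 bases apart. Of 24 lipid droplet and lipolysis genes, 5 and 3 had a peak (65.9 and 79.1), with the β-adrenergic receptor gene Adrb1 at 3.74 in the untreated and Pde3b at 2.65 in the exosome list. Of 25 genes of fatty acid oxidation, 7 and 4 did (82.7 and 86.5). Their strongest peaks were assigned to Hadha (3.58), although Garem2 lay nearer, to Acaa1b (3.33), with Slc22a14 nearer, to Etfa (2.84) and, in the exosome list, to Acadl (2.83), with Kansl1l nearer. Of 25 insulin and glucose genes, 10 and 8 did (71.8 and 95.1). Igf1r (2.90 and 2.96) and Foxo1 (2.92 and 2.02) had peaks in both lists, but at different sites, with summits 82330 and 40128 bases apart. Insr, the insulin receptor gene, had an untreated peak of 2.78.

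Genes of adipocyte secretion and cell state stayed within that range too. Of 20 adipokine genes, 5 had an untreated and 4 an exosome peak (percentiles 83.7 and 97.1). Untreated peaks lay by Sfrp5 (3.42), Rbp4 (3.00, with Pde6c nearer) and Lep, the leptin gene (2.68). Agt had peaks in both lists (2.32 untreated and 2.40 exosome), with summits 9987 bases apart. Of 27 preadipocyte genes, 7 and 6 had a peak (73.0 and 97.4), among them Tcf7l2 (3.15) in the untreated and Col3a1 (2.89) and Cd34 (2.74) in the exosome list. Of 22 thermogenic genes, 8 and 2 did (94.6 and 41.5), with Bmp8b (2.91 and 3.24) in both and Tbx1 (3.07) and Cited1 (3.00) in the untreated list. The Bmp8b summits were 7433 bases apart.

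Genes of other cell types were within the range as well, and of the housekeeping genes those in the exosome list were not. Of 25 trophoblast genes, the type of cell that released the exosomes, 4 had an untreated peak (Gata3 at 2.73, Esrrb at 2.66, Prl3d1 at 2.61 and Hand1 at 2.08) and 0 an exosome peak, at percentiles 41.3 and 4.97. Of 25 genes each, neuronal genes had 6 and 4 (11.2 and 30.2), among them Rbfox3 (3.33), Gria1 (3.13 and 2.77), Map2 (2.98 and 2.44) and Stmn2 (2.82). The Gria1 and Map2 peaks given here lay at least 32209 and 24210 bases from any summit of the other list. Hepatocyte genes had 6 and 1 (74.8 and 22.6), among them G6pc (3.38), Ass1 (3.25), Hnf4a (2.99, with R3hdml nearer) and, in the exosome list, Tdo2 (2.67, with Ctso nearer). Skeletal muscle genes had 8 and 1 (88.0 and 11.8), among them Actn3 (3.37), Neb (3.19), Pygm (3.05, with Rasgrp2 nearer) and Myod1 (2.87). Housekeeping genes had 4 and 6 (50.9 and 99.6), among them Ubc (5.30), Polr2a (2.87) and Gusb (2.71) in the untreated and Pgk1 (2.65) in the exosome list. Replication genes had 4 and 2 (47.6 and 57.1), with Ccnb2 (3.04, with Myo1e nearer), Cdk1 (2.52) and Ccnd1 (2.43, with LTO1 nearer) in the untreated and Mcm6 (2.81) in the exosome list. Of these 30 comparisons with random lists, 1 lay outside the central 95% range, that of housekeeping genes in the exosome list. By the width of the range, 1.5 would lie outside by chance. That number is only nominal, because lists share genes and a lower end of 0 cannot be passed. In the exosome list, differentiation regulators, insulin and glucose, adipokine and preadipocyte genes lay near the upper end (97.4, 95.1, 97.1 and 97.4). The remaining exosome lists, housekeeping genes aside, ran from percentile 4.97 to 86.5.

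**Figure D3:**
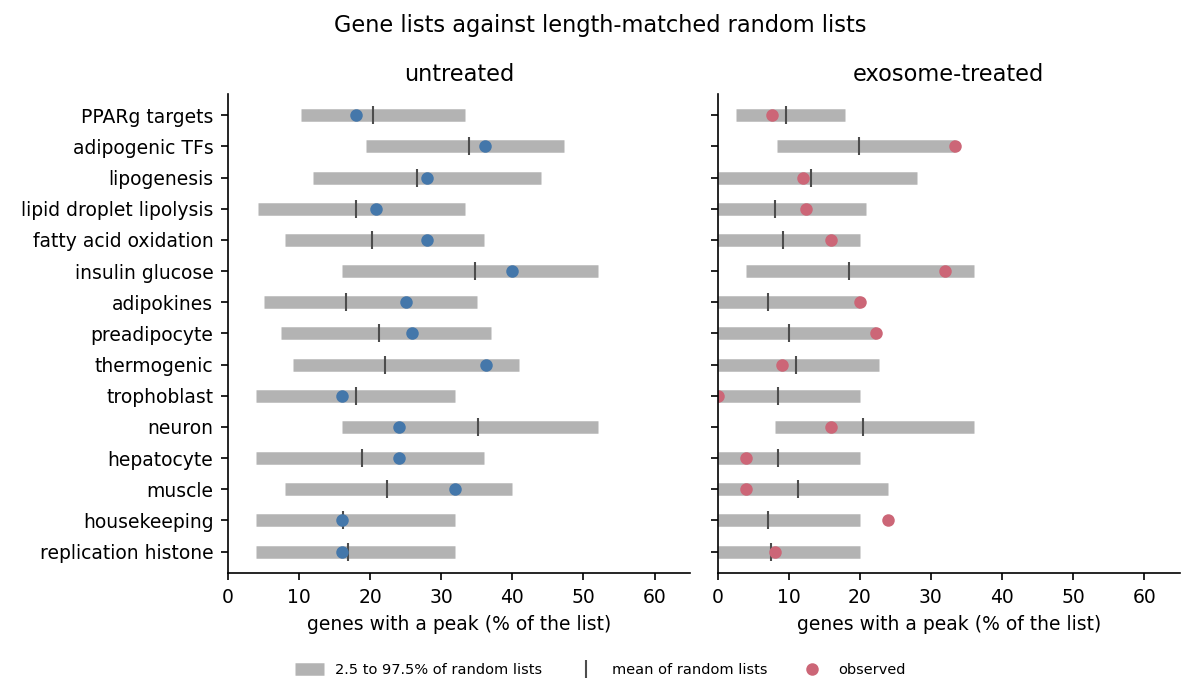
Share of the genes of each list with a peak in the body or within 10 kb (horizontal axis, percent of the list) for 15 gene lists (vertical axis), in untreated and exosome-treated cells. Coloured points are the observed share, grey bars the central 95% range of 10000 random lists matched on gene length, and ticks their mean. The 39 PPARγ targets lie near the mean in both, at percentiles 36.1 and 36.3.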

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

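The test of peak width was set before its result was seen, and the other tests in this part were chosen afterwards. The background recovered from the peak tables reached over 10 times its genome level at 105 untreated and 24 exosome peaks. Around Mdm2, on chromosome 10, it was 38.2 times the genome-wide background in the median of 62 untreated peaks, from 117285222 to 118619854, and 47.5 times in the median of 4 exosome peaks, from 117677367 to 117732756. Outside that region the median was 24.3 times at 43 untreated peaks and 48.4 times at 20 exosome peaks, with maxima of 117.8 and 124.7 times. The first 3.1 Mb of chromosome 9 held 1 of these untreated peaks, at 67.9 times, and 7 of these exosome peaks, with a median of 88.2 times. MACS2 takes this background from the input library.

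The Mdm2 region also holds Slc35e3, Cpm, Nup107, Cpsf6, Lyz1 and Ifng as the nearest genes of its peaks. A collapsed repeat is argued against by an unbroken run of 58 untreated peaks of high background over 389.4 kb, from 117393706 to 117783069, and all 4 exosome peaks in that run had a high background too. More copies of the segment in these cells may be the source, but this stays open. The test asked for over 200 kb in both lists, and the exosome peaks cover 55.4 kb. With only 4 exosome peaks there, that span cannot show how far the background is raised, so the test cannot decide. The peaks were picked by their background, so its median of 38.2 times the genome level says nothing for or against PPARγ binding there. Mdm2 is named after the double minute chromosomes of a 3T3 line in which it was found amplified, but copy number was not measured here.

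The untreated list held 2.85 times as many peaks. A deeper untreated IP is argued against, because background per base of fragment was 1.05 times as high in the exosome IP. Shorter fragments, which let narrower peaks pass in the untreated list, stay open: among peaks as wide as the narrowest exosome peak the ratio was 1.79, between the bounds of 1.5 and 2 set for the test, and this cut could only lower the ratio, as it removed 0 exosome peaks. Lower PPARγ binding after treatment stays open. Known PPARγ targets stood at percentile 36.1 of random lists in the untreated list, and with 1 IP per condition the treatment and the library cannot be told apart.

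The lists shared only 13 peaks. An even scatter is argued against for the untreated peaks, because 31.0% had a neighbour within 10 kb and the highest of 100 shufflings reached 8.8%. Whether the exosome peaks are mostly background fluctuations stays open. For it, only 12 of 3822 exosome peaks reached a q of 0.05, 8 of them over high background. Also for it, the overlap of 13 lay within the range of 100 shufflings, which was the sign set for this cause. It equalled the top of that range, which 6 of 100 shufflings reached. Without peaks of high background, 47 of 100 gave one of 9 or more, as many as were shared. Against an even scatter, 5.42% of exosome peaks had a neighbour within 10 kb (at most 3.85% shuffled) and 47.0% lay in genes (at most 40.9%). Peaks of both lists fell at 819 genes, against at most 647 shuffled and 699.2 expected for genes of the same length. Shuffled positions were not restricted to mappable sequence, so these values cannot tell binding from an uneven background. A move of PPARγ to other sites after treatment stays open, as only 0.314% of exosome peaks reached a q of 0.05 and treatment and library are again the same.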

How the results depend on the processing

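The settings on p, on a q of 0.05, on width, high background and merging within 10 kb were chosen after seeing the data, the rest before the data were examined. No paired analysis was possible because each condition had 1 IP library and no result comes from a test. The motif comparison was not run for want of a genome sequence, and the authors' annotation columns already give the main promoter shares. The median peak rests on 10 or 11 fragments. The untreated list stayed longer under each setting that left exosome peaks, with ratios from 1.79 to 13.5. The causes of the shifts below were not tested.

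Untreated and exosome peaks numbered 23 and 0 at a −log10 q of 5 (no ratio, and no overlap could be taken) and 5 and 1 at a fold enrichment of 5 (ratio 5). They numbered 162 and 12 at a q of 0.05 (ratio 13.5), and 2522 and 801 at a −log10 p of 4 (ratio 3.15). With untreated peaks as wide as the narrowest exosome peak, 6851 remained (ratio 1.79).

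The shares of exosome and untreated peaks that overlap were 0.157% and 0.0551% with at least 50% of both peaks, 0.209% and 0.0735% with summits within 200 bases (8 pairs against 5.74 after shuffling), 1.15% and 0.423% within 1000 bases (44 exosome peaks against 37.5 after shuffling), and 0% and 0% at a fold enrichment of 5, a −log10 p of 4 or among the 1000 strongest. With the strongest peaks, as many as the shorter list, it was 0.0785% of exosome peaks, or 3 against 2.8 after shuffling. No setting with shuffling exceeded its range of chance.

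Within 3 kb of a transcription start lay 14.4% of exosome and 13.8% of untreated peaks, and of the 23 untreated peaks at a −log10 q of 5, 26.1% lay within 1 kb. Genes with a peak in the exosome list, the untreated list and both were 1184, 2686 and 254 with the nearest start within 50 kb, 108, 274 and 3 within 1 kb, and 1353, 2944 and 373 by the gene named in the deposited table. The strongest peaks, as many as the shorter list, gave 2057 untreated genes, fewer than the 2269 of the exosome list, and 402 in both. PPARγ targets that were themselves the gene of the nearest start were 0 exosome and 4 untreated within 50 kb, and 0 and 1 within 1 kb. Exosome peaks 797 bases from Plin2 and inside Mgll did not count there, because their nearest start had no symbol. With the gene body and 10 kb, targets with a peak were 1 exosome and 1 untreated at a −log10 p of 4. They were 2 untreated with the strongest peaks and 0 untreated at a −log10 q of 5. For the other 14 gene lists, 97 counts fell by over 1.5 times and 29 did not. Of these 29, 7 fell by less, 1 rose and the rest were unchanged. Many of the unchanged counts could not move. They include the exosome counts with the strongest peaks, which are the exosome list itself, and the trophoblast exosome count of 0.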

Other observations

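The untreated peaks gathered in dense stretches, and the densest lay at genes outside the adipocyte lists. In bins of 200 kb, 65 held 10 or more untreated peaks, while the exosome list had 0 such bins and shuffled untreated peaks never passed 8. Leaving out regions of high background, the densest was at Lingo1, a neuronal receptor gene on chromosome 9, with 28 peaks and a median fold enrichment of 2.81. It was followed by Hmcn2 on chromosome 2 (27 peaks in the bin, 23 nearest to Hmcn2), the ephrin receptor genes Epha8 and Ephb2 on chromosome 4 (26), Scube3 on chromosome 17 (22), Elfn2 on chromosome 15 (20) and the transcription factor gene Camta1 on chromosome 4 (20). Exosome peaks numbered 1 in the Scube3 bin and 0 in the other 5. The densest exosome bin, at Hace1 on chromosome 10, held 7 peaks. These genes were chosen after their values were seen.

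At a q of 0.05 in the authors' deposited tables, and leaving out high background, untreated peaks fell at 97 protein-coding genes and exosome peaks at 3. Of the 352 genes in the lists written before the data were examined, Cebpd, Hadha and Ubc had such a peak in untreated cells and 0 in exosome-treated cells. The Hadha peak lay nearer to Garem2. With 97 and 3 such genes among all 21887, these counts are too small to set the lists apart from other genes.

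The smallest q in the untreated list belonged to peaks over high background. A peak in Lars2 at chromosome 9, 123461859 to 123462166, reached a −log10 q of 37.9 with 221 fragments over a background of 71.2, and a peak in Gphn on chromosome 12 reached 36.3. They were followed by peaks in Zc3h7a (32.8) and Filip1l (29.8) on chromosome 16.

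A hypothesis that genes read by RNA polymerase III are recovered by the antibody beyond chance was tested with a bound set before the result was seen. Within 1 kb of 467 tRNA and 5S rRNA genes lay 8 untreated peaks, against a mean of 3.48 and at most 9 in 100 shufflings, so the count of all peaks did not exceed chance. Of these 8, 4 lay in a cluster on chromosome 8, from 123600533 to 123622297, and 4 on chromosome 1, from 171064482 to 171074068, and 7 of the 8 reached a q of 0.05, against 162 of 10883, or 1.49%, in the whole list. In a count chosen after seeing the data, at most 1 peak at that q lay near such genes in each of 100 shufflings, but these 7 came from 2 clusters, 2 of them had a high background, and shuffling moves each peak on its own, so chance is not excluded. In the exosome list 2 peaks lay near such genes, 0 of them at that q.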
